A study of Ovis aries with 10 samples.

How the data were processed

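The samples were placentas of Hu sheep at 115 days of gestation, 5 labelled control and 5 labelled restricted. Groups were taken from the treatment label and the title. The treatment protocol field states restricted feeding for every sample, controls included. Per the labels' protocols, RNA was extracted with Trizol and libraries were made from 1 µg of total RNA with the NEBNext Ultra RNA kit. The authors deposited FPKM values for each locus in each of the 10 libraries, per the file headers. The aligner, quantifier, genome build and annotation are not given in the sources used here. The authors' deposited table also holds a mean FPKM per group, a log2 fold change and an FDR, and a further table holds a score (SUM), the sum of the 10 FPKM values, per the file headers. The tool behind the fold change and FDR is not given in the sources used here. The other 14 tables held the same values as the full table to rounding error, and 10 of them are tables of 1 library.

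Of all loci, 2646 were 0 in all libraries. The loci included 15957 with a gene symbol, 4598 named LOC and 6182 without a name. RefSeq (assembly ARS-UI_Ramb_v3.0) was used for names only, and 17633 of 20519 distinct names matched a RefSeq symbol. Read counts were not analysed here, so absolute depth is unknown. Relative depth was read from the smallest steps between FPKM values under 0.15, and ranged from 0.91 to 1.05 of the median library. Ratios were sought only in a narrow range around equal depth, so larger differences could have been missed. The precision at a given FPKM is therefore unknown, and weak loci were filtered instead.

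The choices in this paragraph were made before the data were examined. Genes with a mean of at least 1 FPKM over all libraries were kept, which left 13850. Values as deposited were changed to log2(FPKM + 1) and tested with limma 3.58.1 (statmod 1.5.0, R 4.3.3) with a trend and robust estimation, two-sided, with group as the only term and Benjamini-Hochberg adjustment over all genes. The threshold was an adjusted p of 0.05 with no minimum fold. Of 32 gene lists, 30 had at least 5 tested members and were tested with camera at a preset correlation of 0.01. Erythrocytes (3 tested of 15) and B and plasma cells (1 tested of 14) were too small. Camera with an estimated correlation and fry were run beside it, as was an adjustment over each list alone. List scores (the mean log2 value of the members) were compared by exact two-sided permutation, for which the smallest p is 0.00794.

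Genes were named by a fixed rule, only among those with a symbol that is not a LOC or other placeholder name. It took the 12 genes per direction with the largest change among those past the threshold with separate groups, or, where fewer than 5 passed, the 5 with the smallest p. In each described list the rule named up to 4 members past the threshold, or the 2 with the smallest p. A short set of placental genes was always named. The rule gave 46 genes, and others are marked in the text.

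The labels do not say that the samples come from separate animals, so p values measure the spread between samples. The replicate numbers were checked for pairing, which the labels do not mention. Deviations from the group means correlated between same-numbered libraries at 0.43, 0.48, 0.66, 0.46 and 0.53, all above the bound of 0.1, so the number was also used as a block. After removal of the split between libraries numbered 1 or 3 and the others, these correlations were -0.36, -0.09, -0.05, -0.19 and -0.22.

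Other settings chosen before the data were seen were pseudocounts of 0.1 and 0.5, no filter or a mean of at least 5 FPKM, median-of-ratios, quantile and TPM scaling, limma without trend and robust estimation, array weights, an exact Wilcoxon test, the replicate block, covariates for erythrocyte, trophoblast and stroma genes, only genes with a symbol, and each library left out in turn. Fits with the split as a term (also with median-of-ratios scaling and with an estimated correlation), within each side of the split, and without controls 2 and 5 were added after the data were seen. So was the exact permutation of list scores within the split, for which the smallest p is 0.0167.

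The code was tested on simulated data: 5 runs with 200 changed genes each, based on the 13850 genes. The fit with group only recovered 2.99% of 2-fold, 43.6% of 4-fold and 77% of 8-fold changes, with 4 false calls in all runs. The block recovered 22.4%, 74.6% and 87.3% with 38 false calls, and the split term 43%, 83.3% and 93% with 31 false calls. The simulated values held the split seen in the data, with noise at the spread left after its removal. The higher recovery with the split term was therefore built in, and does not show that this fit suits the real data better. The slope of estimated on simulated log2 differences was 0.916, and 0 of 150 random lists of 20 unchanged genes passed. Noise was drawn independently for each gene, so members of these random lists were not correlated. This count therefore does not show how often camera at the preset correlation falsely calls lists with correlated members. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.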

Results

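RNA was sequenced from the placentas of Hu sheep, with ewes at 115 days of gestation. There were 5 control libraries (normal feeding) and 5 restricted libraries (restricted feeding), numbered 1 to 5 in each group. The deposited table lists, in FPKM (fragments per kilobase of transcript, scaled to the mapped total), 20555 loci with a gene name and 6182 unnamed loci. The FPKM values of a library summed to between 313947 and 502557, and 17496 to 21211 loci lay above 0. The comparison asked how placental gene expression under restricted feeding differed from that under normal feeding.

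IGFBP5, an insulin-like growth factor binding protein, had a mean of 315 ± 262 FPKM in control placentas and 9.86 ± 5.09 FPKM in restricted ones (SD, n = 5 each), and the groups did not overlap. The gap was narrow, with 18.536 FPKM in control 1 and 17.229 FPKM in restricted 1. The chemokine CXCL14 had 125 ± 117 FPKM against 3.95 ± 2.37 FPKM, the retinol receptor STRA6 had 6.1 ± 4.46 FPKM against 0.604 ± 0.445 FPKM, and the complement inhibitor SERPING1 had 15.4 ± 10.2 FPKM against 2.11 ± 1.02 FPKM. RGS2, a regulator of G protein signalling, had 13.1 ± 6.99 FPKM in controls and 1.53 ± 0.448 FPKM in restricted placentas. In the other direction, the cytokine IL11 had 2.47 ± 1.02 FPKM in controls and 9.63 ± 3.18 FPKM in restricted placentas, the cell-surface proteoglycan SDC4 had 490 ± 110 FPKM against 1070 ± 199 FPKM, and the gap junction gene GJA5 had 177 ± 59.4 FPKM against 409 ± 83.1 FPKM. Among genes with a symbol, the remaining ones with the smallest p among higher values were CYP3A24, a cytochrome P450 gene, with 1.94 ± 1.79 FPKM against 10.7 ± 6.15 FPKM, and TMEM150B with 1.98 ± 1.2 FPKM against 5.88 ± 1.17 FPKM. Some unnamed loci had smaller p.

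**Figure D1:**
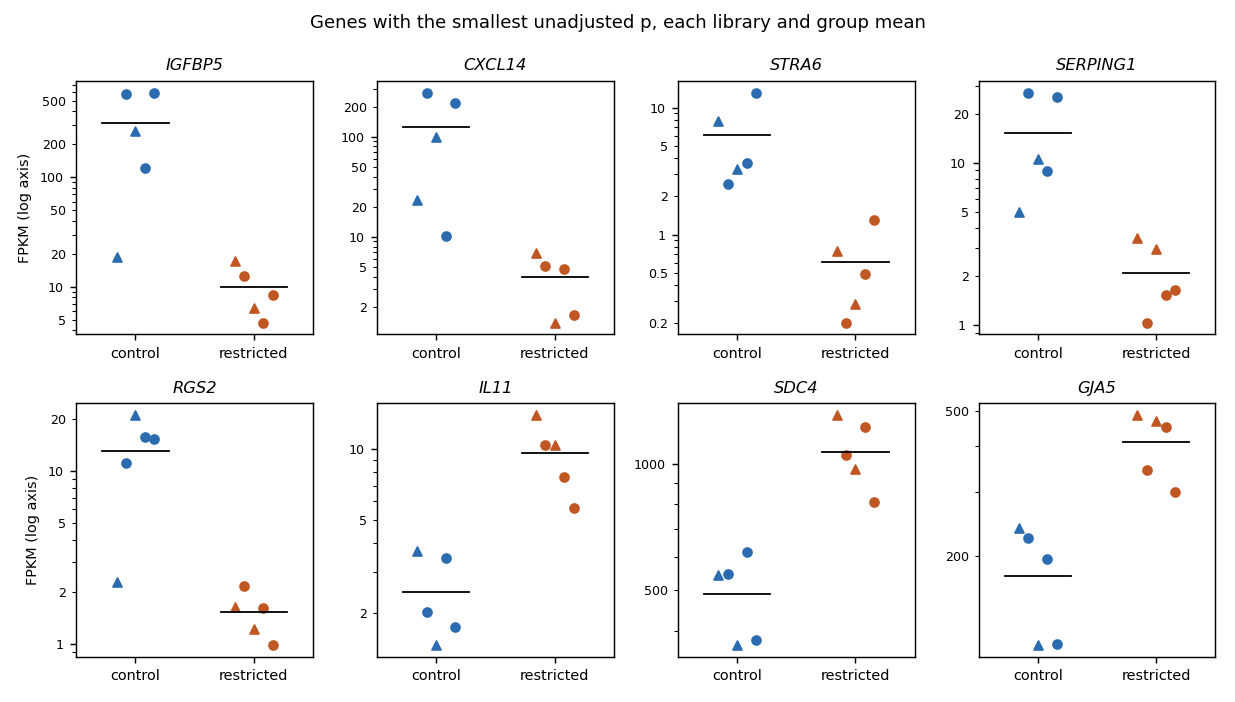
FPKM per library (log axis) of 8 genes with small unadjusted p in control (blue) and restricted (orange) placentas; triangles are libraries numbered 1 or 3, circles the others, and black lines the group means. The control and restricted values of each plotted gene do not overlap, and TMEM150B, whose groups overlap, is not plotted. CYP3A24, whose groups do not overlap and which had 0 FPKM in control 5, is not plotted either. IGFBP5 means are 315 and 9.86 FPKM, with 18.536 FPKM in control 1 and 17.229 FPKM in restricted 1.

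None of these genes passed the test over all genes. The limma-trend fit of 13850 genes gave 0 genes at an adjusted p under 0.05, with 550 genes at an unadjusted p under 0.05 (367 higher and 183 lower in restricted placentas). The balance of directions depended on the setting: 359 higher and 299 lower with median-of-ratios scaling, 419 and 332 with quantile normalization, and 634 and 154 with TPM. It was 528 and 544 with the erythrocyte covariate, 618 and 736 with the trophoblast covariate, and 1911 and 362 with the stroma covariate. The median log2 difference of all genes was 0.09 as deposited, -0.01 with median-of-ratios scaling, 0 with quantile normalization and 0.18 with TPM. Limma without trend and robust estimation gave 0 genes (563 unadjusted). Limma with array weights, which weights each library by its spread, gave 1171 genes (633 higher, 538 lower), and 4 of the 60 groupings that placed 2 of the 4 libraries numbered 1 or 3 in each group, the real one included, gave as many (highest other 1292). The exact two-sided Wilcoxon test gave 0 genes (423 unadjusted). Its smallest possible p is 0.00794, reached only where the groups do not overlap. Far more than 137 such genes would be needed to pass the adjustment, so this 0 adds little. On the log2(FPKM + 1) scale, which understates the change of weakly expressed genes, IGFBP5 differed by -4.22 (SE 0.82, limma adjusted p = 0.645), CXCL14 by -3.97 (SE 0.82, adjusted p = 0.645) and IL11 by 1.61 (SE 0.33, adjusted p = 0.645). In 137 genes the groups did not overlap (108 higher, 29 lower), where groupings of 10 exchangeable libraries would give 0.794% of genes, or 110. The other groupings with 2 of the 4 libraries numbered 1 or 3 in each group had a median of 18 such genes, and 3 of these 60, the real one included, had at least 137 (highest other 160). Without control 1, limma gave 3 genes, all lower: IGFBP5 (log2 difference -5.03, adjusted p = 0.0125), RGS2 (-2.72, adjusted p = 0.0125) and the thyroid hormone carrier TTR (-5.31, adjusted p = 0.0198).

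The libraries differed more between those numbered 1 or 3 and the others than between the groups. Both control and restricted libraries numbered 1 and 3 stood apart from the other 6 along the first principal component, which held 63.7% of the variance. Log-value correlations were 0.87 to 0.95 within these 4 libraries, 0.9 to 0.97 within the 6, and 0.73 to 0.85 between them. The 4 libraries had 17496 to 19605 loci above 0, against 20562 to 21211 in the 6. Across this split 8982 genes passed a limma adjusted p of 0.05, of which 7902 were lower in the 4 libraries. After median-of-ratios scaling, which centres the median gene near 0 by construction, 3876 were lower and 3738 higher. With the split as a term, chosen after seeing the data, limma gave 2 genes past the threshold, both higher in restricted placentas: LOC101119976 (log2 difference 1.41, adjusted p = 0.0237) and an unnamed locus (1.89, adjusted p = 0.043). Within the 6 libraries numbered 2, 4 and 5, limma gave 27 genes, 18 lower and 9 higher, with adjusted p of 0.0495. Lower genes among them, named after their values were seen, included IGFBP5, SERPING1, RGS2, the invariant chain CD74, the complement gene C2, the collagen gene COL1A1 and the microfibril genes MFAP2 and MFAP5. Within the 4 libraries limma gave 0 genes (781 at an unadjusted p under 0.05), and 20 of the 27 genes had the same sign there.

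**Figure D2:**
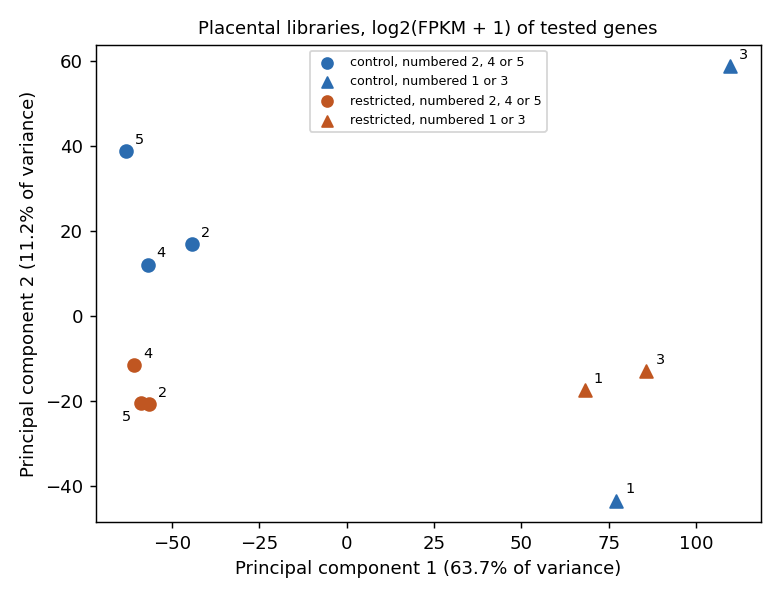
Principal components of log2(FPKM + 1) over 13850 genes, in 10 libraries labelled by number (blue control, orange restricted; triangles numbered 1 or 3). The first axis holds 63.7% of the variance and sets the 4 triangles apart from the 6 circles, with 2 libraries of each group among the 4.

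The uterine serpin SERPINA14 had 15500 ± 19800 FPKM in control and 308 ± 455 FPKM in restricted placentas (SD, n = 5 each), and most of it lay in control 2 (43800 FPKM) and control 5 (28800 FPKM), while control 4 had 50.5 FPKM. The peptide gene GRP had 9590 ± 10400 FPKM against 494 ± 869 FPKM, the secreted phosphoprotein gene SPP1 had 6420 ± 7840 FPKM against 360 ± 183 FPKM, and the leukocyte peptidase inhibitor SLPI had 838 ± 1060 FPKM against 12.6 ± 17.6 FPKM. All were highest in controls 2 and 5. GRP had 25500 and 14000 FPKM there and 42.1 FPKM in control 4, and SLPI had 1576 and 2335 FPKM there and 4.18 FPKM in control 4. SPP1 had 13656 and 16244 FPKM there and 679 to 773 FPKM in the other controls, above the highest restricted value of 491 FPKM. SERPINA14, GRP and SPP1 are named after their values were seen. Of 15 tested members of the uterine epithelium and gland list, 11 had a negative difference and 0 passed over all genes, with 2 lower when adjusted over the list alone (4 with the split as a term, chosen after seeing the data). Its median log2 difference was -1.25, with adjusted p = 2.28e-09 by limma's camera at a preset correlation of 0.01 and adjusted p = 0.223 with an estimated correlation. The mean log2 value of the list was 7.38 ± 1.34 in controls and 5.59 ± 0.69 in restricted placentas (exact two-sided permutation p = 0.0317, Benjamini-Hochberg adjusted over 30 lists p = 0.834).

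More stroma and complement genes had lower than higher values in restricted placentas, with members in both directions. The collagen gene COL1A2 had 98.6 ± 64.2 FPKM in controls and 30.3 ± 19 FPKM in restricted placentas, and COL14A1 had 4.06 ± 3.29 FPKM against 0.77 ± 0.785 FPKM. In the stroma and matrix list 20 of 30 members had a negative difference, 0 passed over all genes and 0 when adjusted over the list alone (8 lower with the split as a term, chosen after seeing the data). Its median was -0.64 (camera adjusted p = 4.67e-06), with adjusted p = 0.835 with an estimated correlation. In the complement and coagulation list 18 of 27 members had a negative difference, 0 passed over all genes, and SERPING1 alone was lower when adjusted over the list alone (6 lower and 1 higher with the split as a term). The complement factor CFB had 3.86 ± 3.56 FPKM in controls and 0.332 ± 0.308 FPKM in restricted placentas. Its list had a median of -0.24 (camera adjusted p = 4.9e-07), with adjusted p = 0.835 with an estimated correlation. The call was also lost in the 4 libraries numbered 1 and 3, where the list mean lay at -0.05 relative to all genes (adjusted p = 0.499), against -0.59 in all libraries and -0.96 without control 1. Without control 1 the stroma and matrix list lay at -0.8, against -0.5 in all libraries. In controls 2 and 5, the libraries with the most SERPINA14, SERPING1 was also highest, at 27.2 and 25.5 FPKM.

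Interferon-induced genes had lower values in restricted placentas in 26 of 29 tested members. The chemokine CXCL9 had 6.34 ± 8.27 FPKM in controls and 0.209 ± 0.203 FPKM in restricted placentas, and XAF1 had 3.76 ± 1.98 FPKM against 1.28 ± 0.637 FPKM. Control 4 had 20.838 FPKM of CXCL9, and the other controls 0.084 to 4.162 FPKM. None passed over all genes or when adjusted over the list alone. With the split as a term, chosen after seeing the data, 9 were lower and 1 higher when adjusted over the list alone. The list's median was -0.43 (camera adjusted p = 3.4e-14), with adjusted p = 0.223 with an estimated correlation. Its mean log2 value was 2.69 ± 0.48 in controls and 2.11 ± 0.26 in restricted placentas (exact two-sided permutation p = 0.0556). Permuted within the split, a test chosen after the split was seen, the exact p was 0.0167, the smallest that this scheme allows, and 0.333 after adjustment over 30 lists. Antigen presentation genes had a median of -0.23 (camera adjusted p = 3.7e-05), and adjusted p = 0.835 with an estimated correlation. The call was also lost in the 4 libraries numbered 1 and 3, where the list mean lay at -0.01 relative to all genes (adjusted p = 0.981), against -0.5 in all libraries, and where DQA differed by 0.2 and CD74 by -1.02. In that list CD74 had 35.6 ± 24.9 FPKM in controls and 6.28 ± 4.89 FPKM in restricted placentas, and the class II gene DQA had 1.83 ± 1.6 FPKM against 0.266 ± 0.222 FPKM. Macrophage markers had a median of -0.19 (camera adjusted p = 0.0281), and adjusted p = 0.835 with an estimated correlation. That call was lost in 16 of 32 other settings and the direction turned in 1, the 4 libraries numbered 1 and 3 (list mean minus that of all genes 0.31, against -0.31 in all libraries). It was lost without control 3 (adjusted p = 0.467), control 4 (0.516), control 5 (0.0524), restricted 2 (0.0902), restricted 3 (0.0568) or restricted 5 (0.063), with list values between -0.72 (without control 1) and -0.06 (without control 4). It was also lost with pseudocount 0.1 (adjusted p = 0.0749), no filter (0.079), median-of-ratios scaling (0.102, or 0.149 with the split term), the trophoblast (0.185) or stroma covariate (0.726) and without controls 2 and 5 (0.0621). Among them C1QB had 57.7 ± 35.5 FPKM in controls and 19 ± 4.7 FPKM in restricted placentas, and the oxidase subunit CYBB had 8.15 ± 7.13 FPKM against 2.09 ± 1.37 FPKM. With group as the only term, 0 members of these lists passed over all genes and 0 when adjusted over the list alone.

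No nutrient transporter in the lists passed limma over all genes, while SLC7A8 has a log2 fold change of 0.65 (rate 0.00992) in the authors' deposited table. The glucose transporters SLC2A1 and SLC2A3 had 250 ± 124 and 132 ± 97.4 FPKM in controls against 392 ± 167 and 215 ± 131 FPKM in restricted placentas (log2 differences 0.66 and 0.92, SE 0.5 and 0.75, limma adjusted p = 1 for both). With the replicate number as a block, their limma p was 0.0119 and 0.00423 unadjusted, and 0.302 and 0.24 adjusted. The amino acid transporters SLC7A5 and SLC38A2 had 4.71 ± 4.48 and 39 ± 25.3 FPKM in controls against 2.32 ± 2.07 and 45.6 ± 26.4 FPKM in restricted placentas. SLC7A5 was 0 FPKM in controls 1 and 3, and 0.118 and 0.143 FPKM in restricted 1 and 3. SLC7A8 and its partner chain SLC3A2 had 90 ± 41.5 and 174 ± 32.1 FPKM against 144 ± 33.1 and 317 ± 151 FPKM. The lactate transporter SLC16A3 had 11 ± 7.26 FPKM against 18.1 ± 4.49 FPKM, and SLC2A8 had 7.53 ± 2.12 FPKM against 11.5 ± 3.66 FPKM. In lipid uptake, the lipoprotein receptor VLDLR had 17.8 ± 5.34 FPKM against 32.3 ± 11.3 FPKM, and the acyl-CoA synthetase ACSL1 had 31.8 ± 15.1 FPKM against 62.2 ± 26.8 FPKM. The camera adjusted p was 0.0826 for glucose transport and glycolysis (median 0.32), 0.821 for amino acid transport (median 0.01) and 0.521 for fatty acid uptake and storage (median 0.23). No member of these 3 lists passed over all genes or when adjusted over the list alone. With the split as a term, chosen after seeing the data, 3 fatty acid uptake members were higher when adjusted over the list alone. Fatty acid uptake passed camera within the 4 libraries numbered 1 and 3 (adjusted p = 0.0448) but not within the other 6 (0.935). With the replicate number as a block, glucose transport and glycolysis passed camera (adjusted p = 0.0366) but had adjusted p = 0.791 with an estimated correlation. CD36 was not analysed here because no row carries that name.

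Of 29 tested oxidative phosphorylation genes, 26 had a negative difference, with a median of -0.19 (camera adjusted p = 0.000732), and adjusted p = 0.835 with an estimated correlation. Most of the tested members were NDUF genes of the first respiratory complex. COX5A was the only cytochrome c oxidase subunit among them, and the listed UQCR genes and CYC1 were absent. The call was lost without control 1 (adjusted p = 0.104) or restricted 4 (0.086), with the erythrocyte covariate (0.477) and in the 4 libraries (0.262). The list mean lay at -0.25 relative to all genes, at -0.15 without restricted 4, at -0.16 without control 1 and at -0.09 with that covariate. ATP5G1 and COX5A, subunits of the ATP synthase and of cytochrome c oxidase, had 41 ± 12.4 and 41.4 ± 12.6 FPKM in controls against 28.4 ± 7.49 and 30.1 ± 6.81 FPKM in restricted placentas. The tricarboxylic acid cycle list had a median of -0.15 (camera adjusted p = 0.0306), and adjusted p = 0.835 with an estimated correlation. It passed without control 3, restricted 2 or restricted 5, and missed the threshold without any other single library (adjusted p from 0.0558 to 0.125). It also missed it with no filter (0.079), with the erythrocyte (0.0856) or stroma covariate (0.187), in the 4 libraries (0.507) and without controls 2 and 5 (0.35). In it IDH2 had 10 ± 3.17 FPKM against 6.46 ± 2.57 FPKM and pyruvate carboxylase (PC) had 6.83 ± 2.05 FPKM against 12.1 ± 5.27 FPKM. Within the 4 libraries numbered 1 and 3, IDH2 differed by 0.38 and ATP5G1 by 0.07 on the log2 scale, the opposite sign. The hypoxia list had a median of 0.33 (camera adjusted p = 0.0258), and adjusted p = 0.835 with an estimated correlation. The call was lost without control 1 (adjusted p = 0.0587), control 3 (0.0704) or restricted 4 (0.208), with the erythrocyte covariate (0.272), in the 4 libraries (0.323) and without controls 2 and 5 (0.0618). Its oxidoreductase ERO1A had 12.1 ± 5.07 FPKM against 21.1 ± 6.16 FPKM, and the vasodilator peptide gene ADM had 570 ± 283 FPKM against 997 ± 289 FPKM. Endothelial markers had a median of 0.46 (camera adjusted p = 0.0426), and adjusted p = 0.835 with an estimated correlation. The call came from the 4 libraries numbered 1 and 3 (camera adjusted p = 3.45e-08), while in the other 6 the list mean lay at -0.15 relative to all genes (adjusted p = 0.306). It was lost in 11 of 32 other settings and the direction turned in 2. Single libraries whose removal lost it were control 1 (adjusted p = 0.892), restricted 1 (0.2), restricted 3 (0.0656) and restricted 4 (0.0703), with list values from 0.09 (without control 1) to 0.57 (without control 4). It was also lost with no filter (adjusted p = 0.119), TPM (0.0757) and the erythrocyte (0.96) or trophoblast covariate (0.0542), and array weights turned it to -0.12. Among these PLVAP had 105 ± 68.9 FPKM against 207 ± 61.2 FPKM and ROBO4 had 13.6 ± 7.07 FPKM against 18.7 ± 4.51 FPKM. Within the 6 libraries PLVAP differed by 0.18 and ROBO4 by -0.05 on the log2 scale, against 1.3 and 0.63 in all libraries. The angiogenesis list had a median of 0.37 (camera adjusted p = 0.0531) and passed with the replicate block (adjusted p = 0.0077), with adjusted p = 0.791 with an estimated correlation and the block. Within the 4 libraries numbered 1 and 3 it had a camera adjusted p of 0.00238, and within the other 6 one of 0.453. The growth factor VEGFA had 45.5 ± 33.8 FPKM in controls and 74.9 ± 44 FPKM in restricted placentas. No member of these 5 lists passed over all genes or when adjusted over the list alone. With the split as a term, chosen after seeing the data, 2 hypoxia and 2 angiogenesis members were higher when adjusted over the list alone.

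Growth factor and hormone genes showed wide spreads, part of which followed the split of the libraries. With the split as a term, the SE of the log2 difference fell from 0.81 to 0.28 for IGF2 and from 0.58 to 0.37 for placental lactogen. Placental lactogen (LOC443319, given the synonyms CSH and PL by RefSeq) had 3610 ± 2190 FPKM in controls and 4620 ± 1800 FPKM in restricted placentas, and IGF2 had 196 ± 135 FPKM against 246 ± 199 FPKM. IGF1 had 2.41 ± 2.5 FPKM against 0.726 ± 0.654 FPKM, and the cortisol-inactivating enzyme HSD11B2 had 2.9 ± 2.06 FPKM against 3.43 ± 2.14 FPKM. The limma adjusted p was 1 for each of these 4 genes. The insulin and IGF signalling list passed camera (adjusted p = 0.00735), with adjusted p = 0.835 with an estimated correlation. That call was also lost in the 6 libraries (adjusted p = 0.273), with array weights (0.128), with the stroma covariate (0.187), with the split term and median-of-ratios scaling (0.109) and without controls 2 and 5 (0.0621). Its median (0.06) and mean (-0.39) had opposite signs, and IGFBP5 was its only member past the threshold when adjusted over the list alone, with 0 over all genes. IGFBP2 in that list had 62.9 ± 94 FPKM against 3.92 ± 2.87 FPKM, with 229.12 FPKM in control 3 and 7.047 to 40.567 FPKM in the other controls. Cell cycle genes had a median of -0.16 (camera adjusted p = 0.0115), and adjusted p = 0.875 with an estimated correlation. The call was lost without control 2 (adjusted p = 0.136), restricted 3 (0.0611) or restricted 4 (0.305), with a mean of at least 5 FPKM (0.105), with the stroma covariate (0.175), in the 4 libraries (0.507) and without controls 2 and 5 (0.443). The list mean lay at -0.22 relative to all genes in all libraries, at -0.09 without restricted 4, at -0.14 without control 2 and at -0.35 without restricted 5. In that list CDC20 had 17.5 ± 5.98 FPKM against 12.2 ± 4.45 FPKM and GINS2 had 12 ± 6.58 FPKM against 16.7 ± 2.5 FPKM. None of its 40 members passed over all genes or when adjusted over the list alone.

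The other tested lists did not pass camera. Cholesterol synthesis had 18 of 19 members with a positive difference and a median of 0.34 (camera adjusted p = 0.148). With the replicate number as a block it passed (adjusted p = 0.0167), and it had adjusted p = 0.791 with an estimated correlation and the block. Within the 4 libraries numbered 1 and 3 its camera adjusted p was 0.0263, and within the other 6 it was 0.53. Median log2 differences were 0.24 for placental steroid synthesis, 0.22 for binucleate and trophoblast cells, 0.14 for glucocorticoid-responsive genes, 0.09 for fatty acid oxidation and 0.09 for the integrated stress response (camera adjusted p = 0.253, 0.532, 0.953, 0.548 and 0.558). Neutrophil markers had a median of -0.23 (camera adjusted p = 0.149). The medians were 0.19 for the unfolded protein response, 0.02 for autophagy, 0.02 for antioxidant defence and 0.1 for inflammatory cytokines. They were 0.03 for smooth muscle, 0.28 for T and natural killer cells and 0.04 for RNA quality and immediate early stress. Camera placed these 7 lists below other genes (adjusted p = 0.806, 0.619, 0.167, 0.245, 0.0834, 0.749 and 0.595). The last of them holds immediate early and heat shock genes and does not measure RNA degradation. CXCL14 was lower when adjusted over the inflammatory list alone, and 0 other members of these lists passed in that way or over all genes. With the split as a term, chosen after seeing the data, more were higher when adjusted over the list alone: 3 in fatty acid oxidation, 1 in glucocorticoid-responsive genes and 1 in the integrated stress response.

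In all, 12 of 30 tested lists passed camera at the preset correlation, 10 of them lower and 2 higher than other genes. With an estimated correlation 0 lists passed camera, and limma's fry gave 0 lists, with 2 at an unadjusted p under 0.05 by each of them. The estimated correlations of the 12 lists ran from 0.2 to 0.74, far above the preset 0.01, so the preset p values overstate the evidence. Without restricted 4 the number at the preset correlation was 7.

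**Figure D3:**
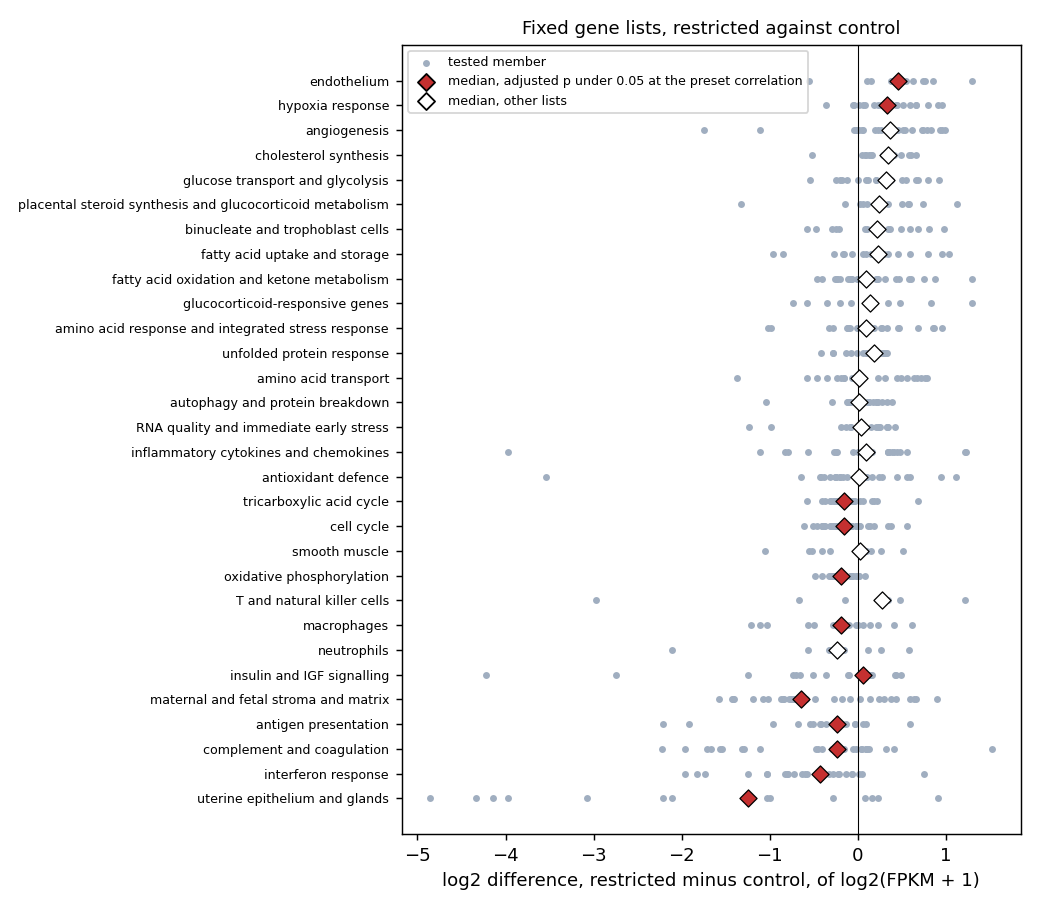
Log2 difference (restricted minus control, of log2(FPKM + 1)) of each tested member (grey points) and the median (diamonds) of the 30 fixed gene lists; red diamonds mark the 12 lists past an adjusted p of 0.05 with camera at the preset correlation. The uterine epithelium and gland list has the lowest median, -1.25, and endothelium the highest, 0.46, and 0 lists pass with an estimated correlation.

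The authors' deposited table holds its own comparison, with a fold change and a false discovery rate for 15779 loci. In the authors' deposited table, a total of 140 loci have a rate under 0.05, of which 81 are lower and 59 higher in restricted placentas. The most negative values with a gene symbol in the authors' deposited table are IGFBP5 (log2 fold change -2.71, rate 3.31e-07), the adhesion receptor ADGRD1 (-2.69, rate 3.31e-07), CXCL14 (-2.51, rate 5.98e-06), STRA6 (-2.25, rate 4.26e-05) and RGS2 (-2.2, rate 5.04e-05). The highest with a gene symbol in the authors' deposited table are MEGF10 (1.43, rate 0.0253), RUFY4 (1.41, rate 0.000506), NUP210 (1.38, rate 0.0306) and IL11 (1.36, rate 0.0371). These genes were chosen by the size of the deposited fold change after the values were seen. Of these loci in the authors' deposited table, 123 entered the fit of 13850 genes, all 123 with the same direction, 108 of them at an unadjusted limma p under 0.05 and 0 at an adjusted p under 0.05. Both comparisons use the same libraries. Among the 70 lower genes with a symbol in the authors' deposited table, 5 belong to the complement and coagulation list (C1S, C2, F13A1, SERPING1 and TFPI2) where 0.169 would fall by chance (one-sided Fisher's exact test over 12047 genes, adjusted p = 3.67e-05). Another member of that list, SERPINE1, is higher in the authors' deposited table (log2 fold change 1.15, rate 0.029). A further 3 belong to the uterine epithelium and gland list (CXCL14, LTF and SPP1; adjusted p = 0.00299) and 3 to the stroma and matrix list (COL14A1, COL1A2 and COL6A3; adjusted p = 0.0136) by the same test on the authors' deposited table. That test treats genes as independent.

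Unnamed loci had higher values in restricted placentas more often than named genes did. The 1952 tested unnamed loci had a median log2 difference of 0.28, against 0.06 for the 11898 tested named genes. In limma, 204 unnamed loci were higher and 18 lower at an unadjusted p under 0.05, against 163 and 165 named genes, with 0 of either at an adjusted p under 0.05. The mean log2 value of the unnamed loci was 1.98 ± 0.24 in controls and 2.27 ± 0.09 in restricted libraries (SD, n = 5 each; exact two-sided permutation p = 0.0159, where the smallest possible is 0.00794). Control 3, at 1.58, lay below the other controls (1.98 to 2.2), and without it the control mean was 2.08 and the difference 0.19 in place of 0.29 (exact two-sided permutation p = 0.0238). This comparison was chosen after the values were seen.

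**Figure D4:**
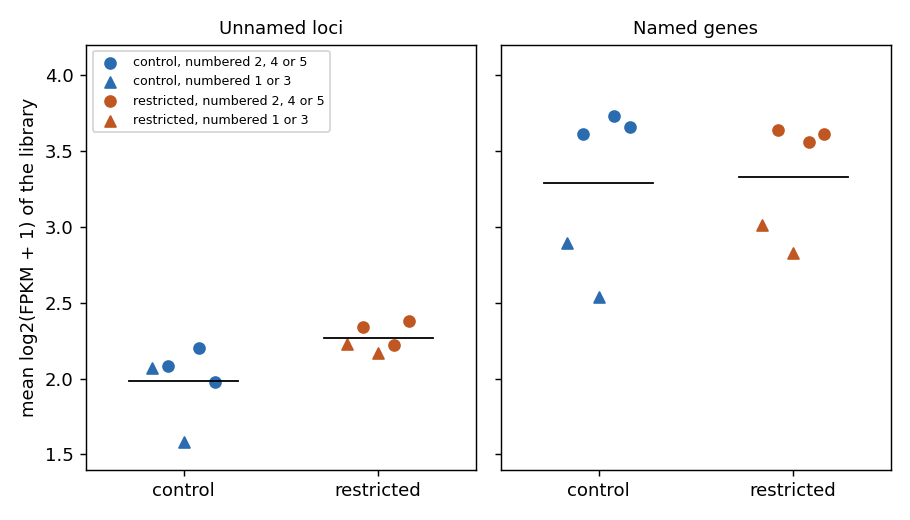
Mean log2(FPKM + 1) per library of tested unnamed loci and of tested named genes, in control (blue) and restricted (orange) placentas; triangles are libraries numbered 1 or 3. The unnamed loci average 1.98 in controls and 2.27 in restricted placentas.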

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

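The tests of depth and of a bias towards short transcripts, the fits that use the split and the groupings balanced across it were chosen after the data were seen. In 152 groups of libraries tested for 1 far from the rest, 8 had such a library, where chance gives about 1 in 20, or 7.6. The measure is the gap to the nearest library over the range of the group, against a limit of 0.71 for 5 libraries. For genes it was taken on log2(FPKM + 1) values, while the values printed below are in FPKM. Among controls, ATP5G1 in control 3 (19.7 FPKM against 42.7 to 51.3, ratio 0.806), XAF1 in control 3 (7.28 FPKM against 2.48 to 3.1, ratio 0.811), ROBO4 in control 1 (2.6 FPKM against 14 to 22.4, ratio 0.762) and C1QB in control 1 (4.69 FPKM against 50.2 to 103, ratio 0.756) lay far from the others. The oxidative phosphorylation list score did so in control 3 (4.65 against 5.43 to 5.68, ratio 0.76). Among restricted libraries, CDC20 in restricted 4 (4.98 FPKM against 11.9 to 16.7, ratio 0.71), SLC2A8 in restricted 1 (17.9 FPKM against 8.87 to 10.7, ratio 0.733) and the antioxidant defence list score in restricted 3 (5.2 against 5.56 to 5.67, ratio 0.767) did so. Of these 8, 7 lie in libraries numbered 1 or 3, the libraries that stand apart.

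The 4 libraries numbered 1 and 3 might differ by lower depth, and their relative depth was read as 1.06 times that of the other 6. That ratio was sought only in a narrow range around equal depth. A much lower depth could have been missed, so depth stays open. A few abundant genes taking up the FPKM total could not account for all of the split, since 84.8% as many genes differed after median-of-ratios scaling. That share compares counts, not the same genes. The excess of lower genes (7902 of 8982) was gone after that scaling (3876 lower, 3738 higher), so for that excess this explanation stays open. A bias towards short transcripts, as from degraded RNA or fragment selection, was the 1 explanation whose prediction was met: 77 ribosomal protein genes, whose transcripts are short, had a median log2 difference of 1.69 towards the 4 libraries after median-of-ratios scaling (quartiles 1.26 and 2.09). With values as deposited it was 0.72, where the median of all genes was -0.78. Ribosomal protein genes may also differ for biological reasons, such as the part of the placenta sampled, and transcript lengths were not available to separate these.

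The lower calls in the authors' deposited table might reflect how much uterine gland tissue each library held. With the gland covariate (SERPINA14 and GRP) beside the split, 71% of 69 lower calls kept at least 50% of their log2 difference, where 75% was set as the limit, so gland content and an effect of feeding cannot be told apart. Part of that could come from the covariate itself, which correlated with group at -0.62. With a stroma covariate 100% kept it, but that covariate left out the list members that were themselves called and correlated with group at only -0.21, so this test excludes nothing and stromal content stays open.

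The higher values of unnamed loci in restricted libraries might come from their low abundance, but their median of 0.28 lay at percentile 100 of 10000 matched sets of named genes (95% of sets between 0.03 and 0.05). More background signal at weak loci would likely raise weak named genes too, yet the ratio of their median to that of weak unnamed loci was -0.125 (-0.05 in 3150 named genes, 0.42 in 3716 unnamed loci). What the unnamed loci are was not tested.

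Regroupings of the libraries showed how often other groupings gave as large a count, the real one included. The count of 0 genes past the threshold could not be tested in this way, because all 100 groupings give at least 0 (highest other 6430). Of these 100 groupings, 30 gave at least 550 genes at an unadjusted p under 0.05 (highest other 7574), 7 gave at least 12 lists (highest other 14) and 57 gave at least 1171 genes with array weights (highest other 9119). These draws ignore the split: 55 of them placed 3 or 4 of the 4 libraries that stand apart on the same side, and 54 of the 57 with as many genes by array weights, 28 of the 30 with as many at an unadjusted p under 0.05 and 0 of the 7 with as many lists were of that kind. The counts of genes in these draws therefore mainly measure the split, while the count of lists does not. In the 60 groupings balanced across the split as the real one is, 3 gave at least 550 genes (highest other 621), 8 gave at least 12 lists (highest other 14) 4 gave at least 1171 genes with array weights (highest other 1292) and 3 gave at least 137 genes with groups that do not overlap (highest other 160), so chance was not excluded for any of these counts at 0.05.

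With the split as a term, 3 of 60 groupings gave at least 1585 genes at an unadjusted p under 0.05 (highest other 1946) and 4 of 60 gave at least 14 lists (highest other 15), which did not exclude chance either. Of the 16 groupings that part all 5 same-numbered pairs, as the real one does, 3 gave as many genes with array weights (highest other 1261) and 2 gave as many at an unadjusted p under 0.05 with the split term (highest other 1829), and 16 groupings are too few for a share under 0.05. In the 6 libraries the real grouping gave 27 genes and the highest other 1 (1 of 10 groupings as large), and 10 groupings are too few for a share under 0.05.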

How the results depend on the processing

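The fits with the split, within 6 or 4 libraries and without controls 2 and 5 were chosen after the data were seen. Of 1369 comparisons of a named gene under an alternative, 1312 kept direction and side of the threshold, 34 moved past it and 23 changed sign. Of 958 comparisons of a gene list, 783 stayed the same, 93 lost the call, 41 gained it and 41 changed sign. The 0 genes past the threshold became 1171 with array weights (633 higher, 538 lower), 4 with the stroma covariate (3 higher, 1 lower), 2 with the split term (2 higher), 1 with the split term and median-of-ratios scaling (1 higher) and 27 in the 6 libraries (9 higher, 18 lower). Leaving out 1 library gave 0 to 3 genes (0 to 0 higher, 0 to 3 lower) and 7 to 12 lists. The 12 lists became 0 with an estimated correlation, 0 with fry and 0 with an estimated correlation and the split term. The first of these runs differs from the main one only in the correlation between members. It was preset at 0.01 and estimated at 0.2 (uterine epithelium and glands) to 0.74 (cell cycle) in the 12 lists. The cause of the other changes was not tested. The replicate block gave 0 genes (0 higher, 0 lower) and 15 lists, and beyond glucose transport, cholesterol synthesis and angiogenesis it changed no other call.

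For genes the values are log2 differences, and for lists the mean log2 difference of the members minus that of all genes. These changed sign, and the cause was not tested. The unfolded protein response list had -0.01 with pseudocount 0.1, 0 with median-of-ratios scaling and 0 with the split term and that scaling. With array weights SLC38A2 had 0, amino acid transport -0.1, fatty acid uptake -0.12, the integrated stress response -0.14, the unfolded protein response -0.04, angiogenesis -0.05 and endothelium -0.12. With the erythrocyte covariate SLC38A2 had -0.35, IGF2 -0.8, HSD11B2 -0.06, amino acid transport -0.26, fatty acid uptake -0.02, glucocorticoid-responsive genes -0.1 and the unfolded protein response -0.31. With the trophoblast covariate SLC38A2 had -0.02, IGF2 -0.26, HSD11B2 0, amino acid transport -0.12 and the unfolded protein response -0.17. With the stroma covariate SLC7A5 had 0.25, the integrated stress response -0.03 and inflammatory cytokines 0.04. In the 6 libraries ROBO4 had -0.05, amino acid transport -0.1, fatty acid uptake -0.08, the integrated stress response -0.07, the unfolded protein response -0.12 and endothelium -0.15. In the 4 libraries IDH2 had 0.38, ATP5G1 0.07, DQA 0.2, C1QB 0.11, SLC7A5 0.18, IGF2 -0.23, glucocorticoid-responsive genes -0.13, inflammatory cytokines 0.09, smooth muscle 0.25 and macrophages 0.31. Without controls 2 and 5 SLC7A5 had 0.48. With 1 library left out the ranges were -0.34 to 0.63 for IGF2, -0.05 to 0.69 for SLC38A2, -0.04 to 0.46 for HSD11B2, -0.13 to 0.15 for amino acid transport, -0.09 to 0.11 for glucocorticoid-responsive genes, -0.03 to 0.11 for the integrated stress response and -0.18 to 0.2 for the unfolded protein response.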

Other observations

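Comparisons across the split of the libraries were chosen after the data were seen. After median-of-ratios scaling, 3738 genes were higher and 3876 lower in the 4 libraries numbered 1 and 3 than in the other 6 (limma adjusted p under 0.05). Of 77 ribosomal protein genes, 74 were higher and 0 lower, and of 29 oxidative phosphorylation genes 18 were higher and 4 lower (list median 0.73). The unfolded protein response list had 17 of 22 members lower (median -1), amino acid transport 14 of 22 lower (median -0.98) and cell cycle 18 of 40 lower (median -0.44). Placental lactogen (LOC443319) had 747.795 FPKM in control 3 and 5766.981 FPKM in control 2.

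The limma array weights were 0.18 and 0.12 for controls 1 and 3 and 0.23 and 0.18 for restricted 1 and 3, against 1.47 to 8.1 in the other 6 libraries. The 1171 genes called with these weights included all 27 genes of the 6 libraries and 104 of the calls in the authors' deposited table. The 5 most abundant loci held 23.3% of the FPKM total in control 3 and 4% in control 4, and unnamed loci held 29% in control 3 and 5.2% in control 5.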
